A study of Escherichia coli with 12 samples.

How the data were processed

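RNA sequencing of 12 libraries was described by the labels as 3 biological replicates each of wild type, rnpA49, pcnB and rnpA49 pcnB strains of Escherichia coli. Per the labels' protocols, RNA was isolated with an RNAsnap procedure and treated with DNase, ribosomal RNA was removed with hybridised probes, random-primed cDNA was made, and libraries were read as single 75 bp ends. The submitters' processing notes name FastQC, STAR and Novoalign, without versions or roles. Per the labels, about 42000000 reads were sequenced per library and reads of the replicates of a strain were merged. The genome build, the annotation, the counting program and the treatment of strand are not given in the sources used here, except that the labels name MG1655 as the genome to which reads were mapped uniquely. Antisense and overlapping genes cannot be told apart without strand, and values of near-identical genes are uncertain.

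The single table used here holds, per the file headers, a mean and a CV for each of 4 strain names, where the mean is a normalized score made by the authors with no unit named. The sum of mean times gene length, with copies counted once, divided by 1000000000, was 1.02 in each strain by the lengths of the reference gene table, close to the value of 1 that RPKM would give, which no source states. The highest CV was 1.73, the square root of 3, which a sample SD over 3 libraries gives when 1 of them is above 0. The fold, a ratio of the highest over the lowest strain mean deposited by the authors, equalled that ratio within 5% on 4444 of the 4445 lines whose 4 means are all above 0. The q-value deposited by the authors has no stated test. Depth per strain column is unknown, so no counting interval was computed.

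No label pairs the strain names with genotypes, and neither column order nor the values of pcnB or rnpA were used to pair them. The 6 genotype contrasts fixed before the data were examined were therefore not run. In their place all 6 pairs of strain names were compared in the same way, a choice made after the table was seen. The table gives no value per library, so the planned tests on library values were not run and the plan for tables with 1 column per strain was followed. A test that needs only means, CVs and the number of libraries could have been run but was left out.

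The table's lines were read from their right end, because 175 lines with several functional terms hold extra commas. Identical lines were merged and features with the same values under different names were counted once, which left 4397 features. Names were matched to the RefSeq gene table of assembly ASM584v2, which served for 4419 of 4436 distinct features to give gene type, length and neighbours. Log2 ratios were taken of the mean plus a pseudocount of 1, without centring, so ratios of features with low values are understated. A feature was called when its ratio was at least 2-fold and the higher of the 2 means was at or above the floor of 17.2, the 25th percentile of the highest mean per line. A call was said to lie beyond the spread when the 2 means were further apart than 2 times the sum of the strains' SDs, each SD being the mean times the deposited CV. No ratio, however large, can meet this rule when 2 times the SD of the higher strain reaches its mean. On data simulated from the deposited means and CVs with 3 libraries per strain, under an assumed log-normal spread that was not checked, the rule called 2 of 2901 unchanged features for SK10521 over SK10153 and found 100 of 100 features at 3-fold and 99 of 100 at 8-fold. For SK10522 over SK10521 it called 8 of 2947 unchanged features. The simulated columns had no offset from each other and the CVs were taken as exact. Calls that arise from the scaling of the columns are therefore not counted here.

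Before the data were examined, 32 gene lists were fixed. Some lists share members, so their results are not separate. For each list the median log2 ratio of the members at or above the floor was set against 10000 random lists of the same size matched on deciles of mean log2 value. Its percentile describes these means and is no test. With 6 pairs this made 180 percentiles, for lists with at least 5 members. A list of pcnB, rnpA and rnpB held 3 members, and a list of ribosomal RNA genes had none at the floor. The rule for named genes, also fixed beforehand, took rnpA, pcnB and rnpB throughout, up to 4 called members with the largest ratio per list (or the largest at the floor where none was called), and the 6 highest and 6 lowest ratios per pair among called features with a mean of at least 77.2. The genes leuA, pheA, thrA, leuZ, metY, cysT, serT, truB, argQ, leuW, thrU, ilvL and ivbL, and the copies that share a value with a named gene, were named after their values were seen. Overlaps between pairs that share no strain were set beside the number that independent lists of the same sizes would share.

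Alternatives were pseudocounts of 0.1 and 5, no floor or a floor at the median, median-centred ratios, trimmed mean scaling, values rescaled without tRNA, rRNA and other structured RNAs, and thresholds of 1.5-fold and 4-fold. Calls restricted to those beyond the spread were added after the data were seen. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.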

Results

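Total RNA of 4 Escherichia coli strains was sequenced after ribosomal RNA depletion. According to the labels these were a wild type, a strain with the temperature-sensitive rnpA49 allele of the protein subunit of RNase P, a strain lacking pcnB, the gene of poly(A) polymerase I, and a strain carrying both mutations. Each was represented by 3 libraries. Cultures grew exponentially in rich medium at 30°C and were then held at 44°C for 1 hour, the temperature used to switch off the mutant RNase P, the ribonuclease that trims the 5′ ends of tRNA precursors. The labels put sequencing at about 42000000 reads of 75 bp per library, of which 76% to 86% mapped uniquely. The deposited table lists 4471 lines, each with a mean and a coefficient of variation (CV) for strains named SK10153, SK10590, SK10521 and SK10522. The sources used here do not pair these names with the genotypes. All results are therefore given by strain name, and none of them is assigned to a pair of genotypes.

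The genes that the study altered, pcnB and rnpA, are given first, with folK and rnpB beside them, as the authors' means without a unit. The pcnB value was 515 in SK10153 (CV 0.07), 37.6 in SK10590 (CV 0.10), 370 in SK10521 (CV 0.02) and 40.9 in SK10522 (CV 0.09). Its operon partner folK, a folate synthesis gene, stood at 237, 31.6, 122 and 36.7 in the same order of strains. For rnpA, the RNase P protein gene, the means were 2373 in SK10153, 2237 in SK10590, 1228 in SK10521 and 1753 in SK10522, with CVs of 0.02 to 0.10. The catalytic RNA of RNase P, rnpB, had means of 42382, 42964, 15107 and 15716 in that order, so that the log2 ratio was -1.49 for SK10521 over SK10153 and -1.45 for SK10522 over SK10590.

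The strain pairs differed in how many features were at least 2-fold apart with the higher mean at or above 17.2. SK10590 and SK10153 were closest, with 99 features higher and 20 lower in SK10590 among 3172. SK10521 and SK10153 were furthest apart, with 308 higher and 281 lower in SK10521 among 3170. SK10522 had 290 features higher and 123 lower than SK10153 among 3237. Against SK10590, 139 features were higher and 289 lower in SK10521 among 3223, and 95 were higher and 104 lower in SK10522 among 3261. Between SK10522 and SK10521, 157 features were higher and 73 lower in SK10522 among 3210. The means lay further apart than 2 times the summed SDs for 103, 485, 366, 389, 175 and 181 of the features called in these pairs, in the order given. No test across libraries was run on these means and CVs, so every call is one of size.

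Part of the direction of these calls depends on the scaling of the columns. The median log2 ratio of the features compared was 0.17 for SK10590 over SK10153, 0.06 for SK10521 over SK10153, 0.23 for SK10522 over SK10153, -0.14 for SK10521 over SK10590, 0.03 for SK10522 over SK10590 and 0.17 for SK10522 over SK10521. With the ratios centred on these medians, SK10590 had 65 features higher and 26 lower than SK10153, so the share called higher was 71.4% instead of 83.2%. SK10522 had 157 higher and 197 lower than SK10153, or 44.4% instead of 70.2%. The other splits that moved by over 10 percentage points were 175 higher and 218 lower for SK10521 over SK10590 (44.5% instead of 32.5%) and 103 higher and 105 lower for SK10522 over SK10521 (49.5% instead of 68.3%). Trimmed mean scaling gave shares of 68.2%, 44.4%, 45.2% and 48.6% for these 4 pairs. For SK10521 over SK10153 the majority changed side, from 308 higher and 281 lower to 278 and 309 with centred ratios and 279 and 313 with trimmed mean scaling. SK10522 over SK10590 had 87 higher and 111 lower with centred ratios. Centred counts are given below for gene groups where they differ.

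Ratios that share no strain were set side by side. The pairings below are not separate results, because all use the same strain columns. On the same features, the covariance of each pairing is fixed by those of the others. It was 0.427 and 0.433 for the first 2 pairings and -0.008 for the remaining one. The first 2 thus reflect the same contrast, of SK10521 and SK10522 with SK10153 and SK10590. The log2 ratios of SK10521 over SK10153 and of SK10522 over SK10590 had a Pearson r of 0.69 and a Spearman rho of 0.53 across 3141 features, which are not independent replicates. In both ratios 69 features were at least 2-fold higher, where independent lists would share 8.66, and 74 were at least 2-fold lower, where they would share 8.76. Only 5 features were called in opposite directions, against 17.5 for independent lists. The ratios of SK10522 over SK10153 and of SK10521 over SK10590 had r 0.66 and rho 0.53 across 3170 features, with 80 features higher in both (11.7 for independent lists), 85 lower in both (10.3) and 15 called in opposite directions (29.2). The remaining pairing, SK10590 over SK10153 with SK10522 over SK10521, had r -0.03 and rho -0.09 across 3092 features, with 19 features higher in both (4.64 for independent lists), 2 lower in both (0.35) and 10 called in opposite directions (2.72).

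Features of tRNA genes were among those furthest apart between strains. The table holds 85 tRNA names with 47 distinct sets of values, since identical copies carry the same numbers, and 39 sets reached the floor. Of these 39, 13 were at least 2-fold higher and 4 at least 2-fold lower in SK10521 than in SK10153, and 13 were higher and 0 lower in SK10522 than in SK10153. Against SK10590, 15 sets were higher and 2 lower in SK10521 (17 and 0 with centred ratios), and 18 were higher and 0 lower in SK10522. SK10590 and SK10153 had none at least 2-fold apart with the deposited scaling and 1 lower in SK10590 with centred ratios. The shared value of glnU and glnW, glutamine tRNA genes, was 11349 in SK10153 (CV 0.12), 11584 in SK10590 (CV 0.05), 231297 in SK10521 (CV 0.14) and 263965 in SK10522 (CV 0.01). The serine tRNA gene serV had means of 3578, 3606, 58452 and 68686, and the valine tRNA set of valT and 4 further names had 10429, 9609, 149905 and 174100. The leucine tRNA genes leuP and leuW were at least 3.21 higher on the log2 scale in SK10521 and SK10522 than in either other strain.

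Between SK10522 and SK10521, 3 tRNA sets were higher in SK10522, and 1, the alanine tRNA genes alaW and alaX, with centred ratios. Their shared mean was 84.1 in SK10153, 80.4 in SK10590, 612 in SK10521 and 4668 in SK10522, which made a log2 ratio of 2.93 between SK10522 and SK10521. The 4 sets lower in SK10521 than in SK10153 were leuZ, metY, cysT and serT. Of these, leuZ lay beyond the spread, with means of 361 and 160 and a log2 ratio of -1.17. The initiator tRNA gene metY had 2791 in SK10153 and 1343 in SK10521. Gene length multiplied by value and summed over tRNA features, with copies counted once, made up 0.553% of the table's total in SK10153, 0.495% in SK10590, 4.69% in SK10521 and 5.39% in SK10522. Values shared between tRNA copies are uncertain as to which copy they come from. Ribosomal RNA was represented by 7 names with a highest value of 0.01 and was not compared.

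**Figure D1:**
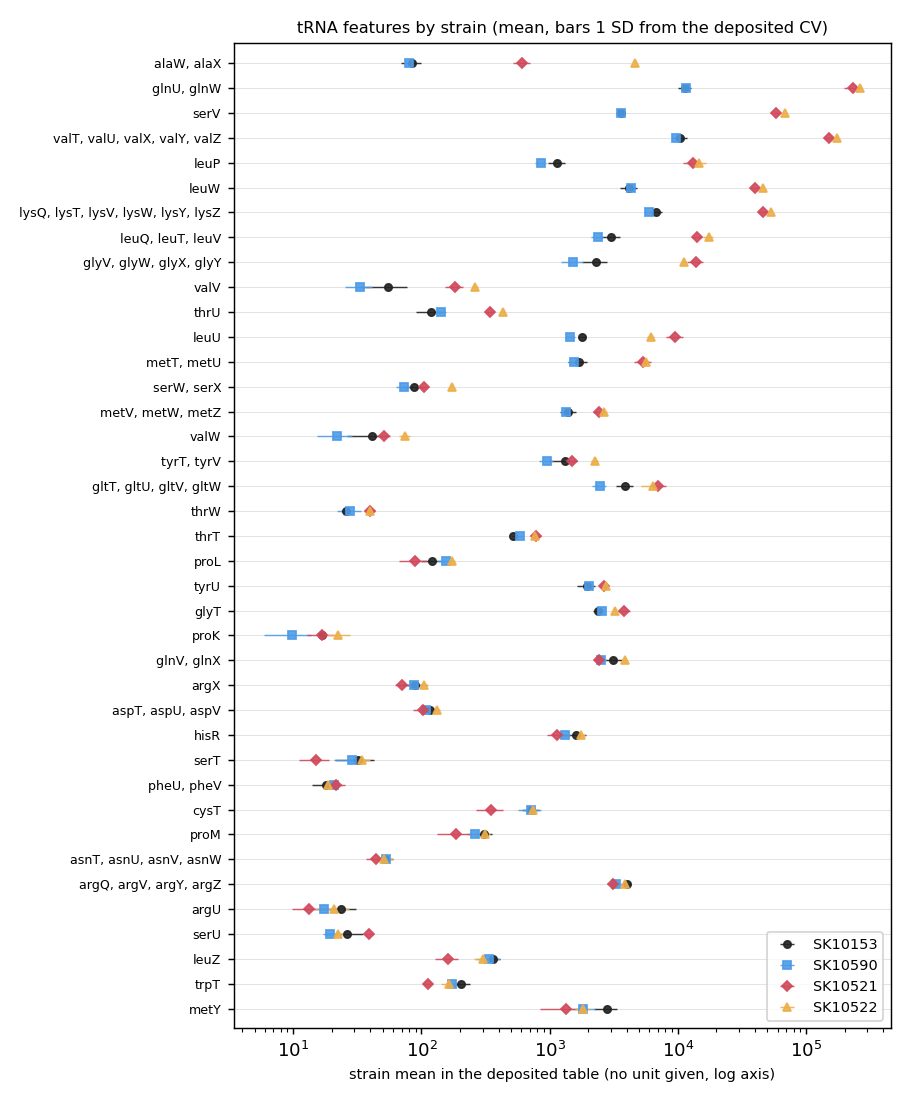
Strain means of the 39 tRNA value sets at or above the floor, on a log axis without a unit, with 1 marker shape and colour per strain and horizontal bars of 1 SD taken from the deposited CV. In sets such as glnU and glnW the means of SK10521 (231297) and SK10522 (263965) stand far to the right of those of SK10153 (11349) and SK10590 (11584), while the markers of the argQ, argV, argY and argZ set lie close together.

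A list of 18 genes in operons for which RNase P cleavage has been reported held members far apart in both directions. In SK10521, 9 members were higher and 8 lower than in SK10153, and in SK10522, 8 were higher and 8 lower (7 and 8 with centred ratios). The list's median log2 ratio of 2.01 for SK10521 over SK10153 thus falls in the gap between the 9 higher members and the rest. No member lay near it. The 8 his genes and secG made up the higher members in SK10521. The preprotein translocase gene secG, which lies next to leuU, had a mean of 4297 in SK10153, 3739 in SK10590, 78649 in SK10521 and 51235 in SK10522, with CVs of 0.02 to 0.10. The tryptophan permease gene tnaB stood at 525 (CV 0.49), 414, 12.4 and 53.4, and the ribose transporter gene rbsC at 266, 218, 17.1 and 18.3. Among 17 genes beside or within tRNA operons, 6 were higher and 1 lower (6 and 0 with centred ratios) in SK10521 than in SK10590. In SK10522, 7 were higher and 0 lower than in SK10590. These were led by secG, glyW and valV, which were all counted above, glyW and valV as tRNA sets and secG with the RNase P operons. In SK10590, 1 member, tpr, was lower than in SK10153, at 61.6 against 134 (CVs 0.25 and 0.37), which did not lie beyond the spread, and 2 members were lower with centred ratios.

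Of 31 genes in biosynthetic operons that are controlled by transcription attenuation, 25 were at least 2-fold higher and 0 lower in SK10521 than in SK10153, all of them beyond the spread, and the median log2 ratio was 2.65. In SK10522, 25 were higher than in SK10153 (22 with centred ratios) with a median of 1.91. Against SK10590 the counts were 23 higher in SK10521 and 23 higher in SK10522 (24 and 22 with centred ratios). These 4 medians stood at the 100th percentile of 10000 random lists matched on mean value. The histidine gene hisG had means of 24.7 in SK10153 (CV 0.06), 26.8 in SK10590 (CV 0.07), 2051 in SK10521 (CV 0.07) and 214 in SK10522 (CV 0.12). The next gene, hisD, had 16.4, 23.0, 1386 and 158. The threonine gene thrA followed the same order, with 43.3, 57.7, 1318 and 221. Between SK10522 and SK10521, 11 members were lower and 1 higher in SK10522 (12 and 1 with centred ratios). The higher one was pheA, of phenylalanine synthesis, with 251 in SK10521 and 589 in SK10522. The leucine gene leuA had 5.35, 7.51, 53.2 and 67.6 in SK10153, SK10590, SK10521 and SK10522. The his genes of this list are also members of the list of operons with reported RNase P cleavage.

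Of 18 genes of sulfate uptake and cysteine synthesis, 15 were at least 2-fold higher in SK10521 than in SK10153 and 15 than in SK10590, with median log2 ratios of 4.51 and 3.99. In SK10522, 12 were higher than in SK10153 and 12 than in SK10590, with medians of 2.09 and 1.75. In SK10522, 14 were lower than in SK10521. The sulfate transport gene cysU had a mean of 3.48 in SK10153, 5.06 in SK10590, 299 in SK10521 (CV 0.51) and 26.6 in SK10522 (CV 0.70). The ATP sulfurylase gene cysD had 4.07, 5.71, 312 (CV 0.66) and 38.6 (CV 0.50), and the sulfite reductase gene cysJ had 5.84, 7.17, 351 and 35.3. Because of these CVs only 4 of the 15 calls between SK10521 and SK10153, and 4 of the 15 between SK10521 and SK10590, lay beyond the spread. A CV of 0.50 or more in the strain with the higher mean keeps a call from meeting that rule at any fold. Failing it therefore does not show that the strains overlap. For SK10522 it was 4 of the 12 calls against SK10153, 3 of the 12 against SK10590 and 2 of the 14 against SK10521. The median CV of the list was 0.54 in SK10521 and 0.39 in SK10522, against 0.09 in SK10153 and 0.06 in SK10590.

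Of 64 genes of sugar transport and use, 26 were at least 2-fold lower and 7 higher in SK10521 than in SK10153 (29 and 7 with centred ratios), and 29 were lower and 0 higher than in SK10590 (25 and 1 with centred ratios). In SK10522, 20 were lower and 5 higher than in SK10153 (25 and 4 with centred ratios), and 18 were lower and 0 higher than in SK10590. In SK10521 and SK10522 against SK10153 or SK10590, malK, lamB and malE had the lowest ratios among features with a mean of at least 77.2. The transporter gene malK had a mean of 1545 in SK10153 (CV 0.36), 768 in SK10590 (CV 0.24), 5.74 in SK10521 (CV 0.53) and 17.0 in SK10522 (CV 0.21). The maltoporin gene lamB had 1183, 959, 9.98 and 13.5, and malE, the periplasmic maltose-binding protein gene, had 1541, 1057, 12.3 and 22.7. The sorbitol operon differed along another line. Its srlD gene had 130 in SK10153, 1431 in SK10590, 539 in SK10521 (CV 0.31) and 1345 in SK10522. Between SK10590 and SK10153, 4 of the 64 genes were higher, all of them srl genes, and 1, malK, was lower without lying beyond the spread.

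**Figure D2:**
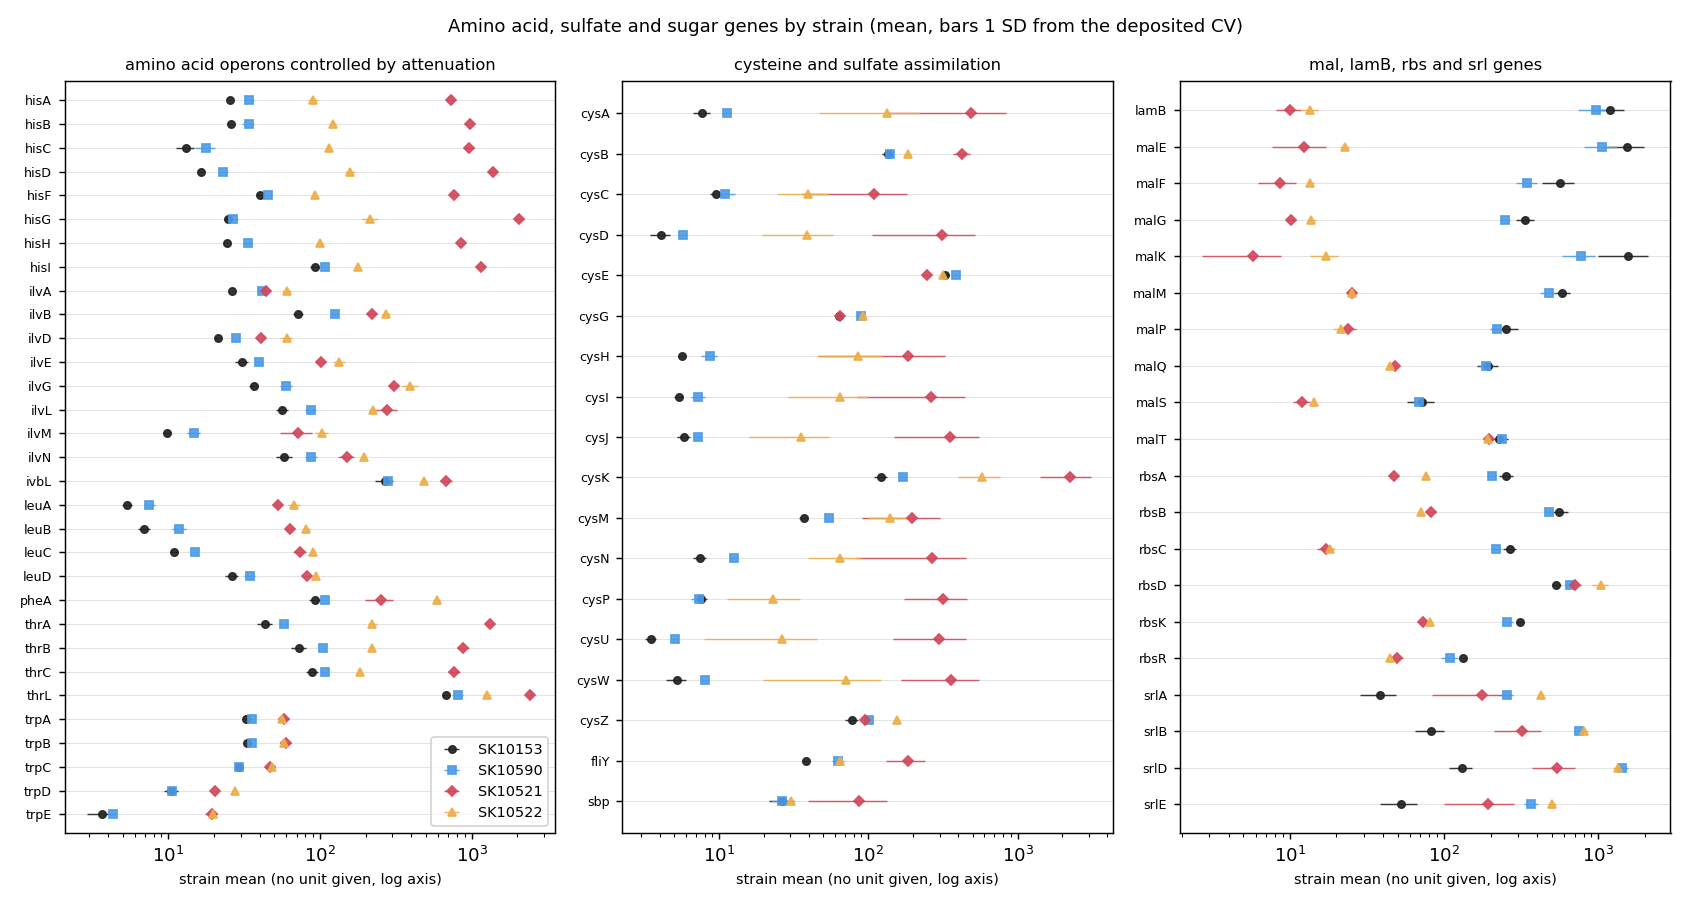
Strain means of genes in attenuation-controlled amino acid operons (left), sulfate and cysteine genes (middle) and mal, lamB, rbs and srl genes (right), on log axes without a unit, with bars of 1 SD from the deposited CV. The his genes have their highest means in SK10521, such as 2051 for hisG, and the bars of the cys genes in SK10521 and SK10522 are wide, with a CV of 0.51 and 0.70 for cysU.

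Of 43 genes regulated by the iron repressor Fur, 24 were lower and 5 higher in SK10521 than in SK10153 (25 and 5 with centred ratios). In SK10522, 6 were lower and 3 higher (9 and 2 with centred ratios). Between SK10590 and SK10153, 2 were higher and 2 lower in SK10590 (1 and 2 with centred ratios). The ferric citrate receptor gene fecA had means of 247 in SK10153, 204 in SK10590, 21.8 in SK10521 and 68.4 in SK10522, and the enterobactin synthesis gene entC had 53.5, 61.0, 8.51 and 40.2. On the opposite side, the ribonucleotide reductase genes nrdH and nrdI were 2.96 and 2.99 higher on the log2 scale in SK10521 than in SK10153. Of 31 genes of aerobic respiration and ATP synthase, 18 were lower and 4 higher in SK10521 than in SK10153, and 5 were lower and 4 higher in SK10522 (11 and 3 with centred ratios). The NADH dehydrogenase I gene nuoH had 410, 374, 117 and 186 in SK10153, SK10590, SK10521 and SK10522. The single-subunit NADH dehydrogenase gene ndh had 116 (CV 0.62), 104, 596 and 273. Of 18 citric acid cycle genes, 6 were lower in SK10521 than in SK10153 (7 with centred ratios) and 9 were lower in SK10522 (13 with centred ratios), and 0 were higher. Against SK10590, 1 was lower in SK10521 and 5 were lower in SK10522 (1 and 6 with centred ratios). The 2-oxoglutarate dehydrogenase gene sucA had 780, 683, 294 and 286.

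Among 31 genes of anaerobic respiration and fermentation, 6 were lower and 1 higher in SK10521 than in SK10153, and 4 were lower in SK10522 (5 with centred ratios). Of these calls with the deposited scaling, 2 of the 7 for SK10521 and 0 of the 4 for SK10522 lay beyond the spread. The nitrate transporter gene narK had means of 67.9 (CV 0.55), 41.4, 6.07 and 29.4 in SK10153, SK10590, SK10521 and SK10522. Of 20 genes of glycolysis and gluconeogenesis, 3 were higher and 1 lower in SK10521 than in SK10153. In SK10522 the split was 2 higher and 0 lower, which turned to 0 higher and 3 lower with centred ratios. The aldolase genes went opposite ways, with fbaB at 56.9 in SK10153 and 286 in SK10521 and fbaA at 1675 and 628. Of 27 genes of purine and pyrimidine synthesis, 10 were lower and 0 higher in SK10521 than in SK10153 (11 and 0 with centred ratios), and 10 were lower than in SK10590. In SK10522, 5 were lower and 1 higher than in SK10153 (6 and 0 with centred ratios). The carbamoyl phosphate synthetase gene carB had 704, 516, 99.7 and 84.7, and the aspartate carbamoyltransferase gene pyrB had 78.3, 60.7, 9.76 and 11.0. The purine gene purM stood at 153, 188, 45.2 and 175. Of 25 arginine, methionine and lysine genes, 5 were higher and 2 lower in SK10521 than in SK10153. The lower ones were carA and carB, and carB is the gene already named under pyrimidine synthesis. The higher ones included lysA, of lysine synthesis, with 18.4 in SK10153, 18.4 in SK10590, 158 in SK10521 and 22.1 in SK10522.

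Of 27 genes of the general stress response under RpoS, 24 had their lowest mean in SK10153. Compared with SK10153, 14 were at least 2-fold higher and 0 lower in SK10590 (12 with centred ratios), 15 were higher in SK10521, and 8 were higher in SK10522 (3 with centred ratios). The median log2 ratio over SK10153 was 1.05 for SK10590, 1.25 for SK10521 and 0.77 for SK10522. The peroxide resistance gene osmC had means of 46.9 in SK10153, 152 in SK10590, 295 in SK10521 and 160 in SK10522, and the DNA protection gene dps had 336, 915, 1435 and 903. The acid resistance gene hdeA had 44.8, 188, 60.8 (CV 0.98) and 54.6. Of 12 curli and fimbriae genes, 7 were higher and 0 lower in SK10590 than in SK10153 (6 with centred ratios), 7 were higher and 1 lower in SK10522, and 4 were higher and 2 lower in SK10521. The fimbrial subunit gene fimA had 217, 962, 473 and 1016. The adhesin gene flu, for antigen 43, had 972, 827, 96.6 (CV 0.66) and 42.4.

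Of 27 genes of the heat shock regulon, 6 were lower and 0 higher in SK10522 than in SK10521 (7 with centred ratios), 6 were lower than in SK10590, and 3 were lower and 1 higher than in SK10153 (5 and 0 with centred ratios). The chaperonin gene groL had means of 4135 in SK10153, 3912 in SK10590, 4112 in SK10521 and 1375 in SK10522, and groS had 2069, 2032, 1953 and 752. In SK10521, 4 heat shock genes were higher than in SK10153, among them ibpB and ibpA, whose CVs in SK10153 were 0.49 and 0.56, and 2 of the 4 calls lay beyond the spread. Of 19 genes of the sigma-E envelope stress regulon, 4 were higher in SK10521 than in SK10153 and 2 in SK10522, with rseA at 752, 1163, 3397 and 2011 and rpoE at 625, 933, 2580 and 1609. Of 13 cold shock genes, 6 were lower and 1 higher in SK10521 than in SK10153, and 5 were higher in SK10522 than in SK10521. The cspI gene had 175, 104, 72.8 and 262, with CVs of 0.34 to 0.65, and 2 of the 7 calls between SK10521 and SK10153 and 1 of the 5 between SK10522 and SK10521 lay beyond the spread.

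Of 54 ribosomal protein genes, 8 were lower in SK10521 than in SK10153 (11 with centred ratios), and in the other 5 pairs 0 were at least 2-fold apart under the deposited, centred or trimmed mean scaling. The 8 genes belonged to the S10 operon, whose first gene rpsJ had 9119 in SK10153 (CV 0.26), 6863 in SK10590, 3513 in SK10521 and 6113 in SK10522, and 1 of the 8 calls lay beyond the spread. None of 16 translation factor genes was called in any pair under these scalings. With the deposited scaling the largest ratio was that of prfA, at 0.73 for SK10522 over SK10521. Of 23 aminoacyl-tRNA synthetase genes, 2 were higher and 1 lower in SK10522 than in SK10153. The phenylalanine genes pheS and pheT had 494 and 527 in SK10153 and 1302 and 1505 in SK10522, and lysU, a lysine synthetase gene, had 1198 and 551. Among 27 tRNA modification genes, 1 was higher in SK10522 than in SK10153, miaB, at 492 against 241. With centred ratios miaB was no longer called and truB, at 264 against 518, was called lower instead. In SK10521 tmcA was lower than in SK10590, at 46.6 against 115. Of 32 ribonuclease and RNA decay genes, pcnB, rnpB and the toxin gene yoeB were called in 1 or more pairs with the deposited scaling. With centred ratios rnpA was also called lower in SK10521 than in SK10153, 3 members in place of 2 were lower in SK10522 than in SK10153, and yoeB was no longer called between SK10522 and SK10590.

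Small and structured RNAs went both ways, with 29 at the floor from a list of 47. Of 29, 6 were lower and 2 higher in SK10521 than in SK10153 (6 and 1 with centred ratios), and 5 were higher and 2 lower in SK10522 than in SK10153 (1 and 2 with centred ratios). The CsrA-binding RNA csrB had means of 2723 in SK10153, 1792 in SK10590, 456 in SK10521 (CV 0.29) and 2749 in SK10522. The small RNA glmZ had 1870, 3545, 1344 and 1579. Of 39 toxin and antitoxin genes, 9 were higher and 0 lower in SK10522 than in SK10153 (6 and 1 with centred ratios), and 7 were higher and 1 lower in SK10521. The toxin gene relE had 108, 190, 254 and 412, and hokD had 94.7, 199, 229 and 406. Of 22 prophage genes at the floor, from a list of 55, 6 were higher and 1 lower in SK10522 than in SK10590 (5 and 1 with centred ratios). They included cohE, with 92.9 in SK10590 and 277 in SK10522. Of 17 outer membrane and lipoprotein genes, 5 were lower in SK10521 than in SK10153, with the nucleoside channel gene tsx at 4209 and 1116. Of 7 phage shock genes, 1 was higher in SK10521 and 1 in SK10522 than in SK10153 (0 and 0 with centred ratios); pspF had 10.5 in SK10153 and 25.9 in SK10522. Of 52 listed genes of flagella and chemotaxis only 8 reached the floor. Among these, trg was lower in SK10521, at 29.4 against 63.1 in SK10153, without lying beyond the spread. Its mean of 62.4 in SK10522 was called higher than in SK10521 and lay beyond the spread, but was not called with centred ratios. Among 21 SOS genes, dinD alone was called with the deposited scaling, with 16.3 in SK10521 and 34.5 in SK10522, again not beyond the spread. With centred ratios dinD was not called, and recX was called lower in SK10521 than in SK10153, at 23.1 against 46.5.

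**Figure D3:**
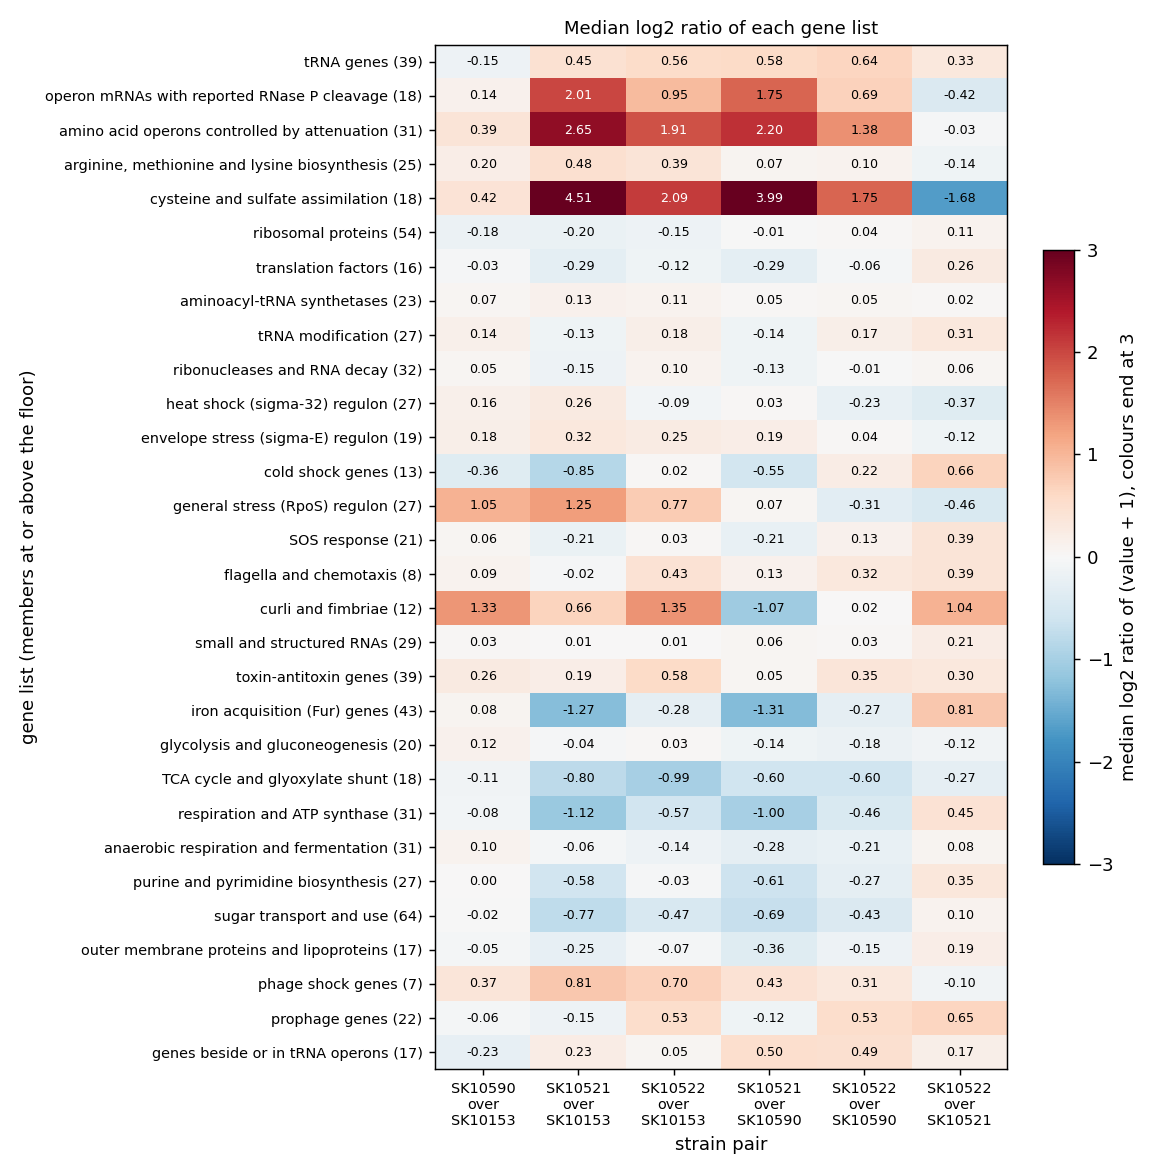
Median log2 ratio of (value + 1) of each gene list with at least 5 members at or above the floor (vertical axis, members in brackets) in each of the 6 strain pairs (horizontal axis), with colours from blue for lower to red for higher in the first-named strain. The sulfate list reaches 4.51 for SK10521 over SK10153 and the iron list -1.31 for SK10521 over SK10590, while the ribosomal protein list lies between -0.20 and 0.11.

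The features at the ends of each ratio, among those with a mean of at least 77.2 in either strain, were largely the groups already described. For SK10590 over SK10153 the highest were srlD, srlB, srlE, srlA, srlM and ymdF, at log2 ratios of 2.39 to 3.45, and the lowest were pcnB, yjiY, folK, yjiX, fhuC and yjjZ. Of these, yjiY (614 in SK10153 with a CV of 0.80 and 48.9 in SK10590), yjiX and yjjZ did not lie beyond the spread. For SK10521 the highest over SK10153 were hisD, hisG, hisC, cysU, cysD and cysW, and over SK10590 yeeE took the place of cysW. The lowest in SK10521 against either strain were malK, malE, lamB, malF, tnaB and malG. For SK10522 over SK10153 the highest were alaX, glnW, serV, valT, cysA and cysH, and over SK10590 leuP and secG replaced cysA and cysH. The lowest in SK10522 were malK, lamB, malE, malF and flu, joined by malG against SK10153 and by malM against SK10590. For SK10522 over SK10521 the highest were alaX, csrB, xanP, bglJ, purM and yagF, at 1.84 to 2.93, and the lowest were cysP, cysU, cysJ, hisG, pcnB and hisD, at -3.73 to -3.12. Of the features named for these 5 pairs, those not beyond the spread were cysU, cysD, cysW and tnaB for SK10521 over SK10153, cysU and cysD for SK10521 over SK10590, cysA for SK10522 over SK10153, and cysP, cysU and cysJ for SK10522 over SK10521.

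The authors' deposited table carries a fold of the highest over the lowest strain mean and a smallest q-value for each line. The authors' deposited table marks 66 lines, with folds of 10.6 to 269 and q-values up to 0.0795. Their highest mean is in SK10521 for 27 lines, SK10522 for 21, SK10153 for 15 and SK10590 for 3. A q-value of 0.05 or less stands on 3913 lines of the authors' deposited table, or 87.5%. The sources used here give neither the test nor the comparisons behind that q-value.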

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

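The counts of features at least 2-fold apart stayed within 1.5 times the reported count in all 6 pairs with pseudocounts of 0.1 or 5, with no floor, with centred ratios, with trimmed mean scaling, without structured RNAs, and, in an alternative added after the data were seen, with calls beyond the spread alone. Centring and trimmed mean scaling moved the split between higher and lower, as given with the counts. They also changed which features were called. Centring kept 280 of 413 calls for SK10522 over SK10153, 85 of 119 for SK10590 over SK10153 and 176 of 230 for SK10522 over SK10521. It kept 357 of 428 for SK10521 over SK10590, 559 of 589 for SK10521 over SK10153 and 191 of 199 for SK10522 over SK10590. A floor at the median left 70 features in place of 119 for SK10590 over SK10153, 269 in place of 413 for SK10522 over SK10153, and 147 in place of 230 for SK10522 over SK10521, since fewer features are compared.

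The threshold moved every count by construction. At 1.5-fold, SK10590 over SK10153 had 471 features, SK10521 over SK10153 had 1264, SK10522 over SK10153 had 1147, SK10521 over SK10590 had 957, SK10522 over SK10590 had 562 and SK10522 over SK10521 had 695. At 4-fold the counts in that order were 15, 135, 89, 99, 60 and 33. Features called the same way in both ratios of a pairing numbered 143 for SK10521 over SK10153 with SK10522 over SK10590, 362 at 1.5-fold and 50 at 4-fold. For SK10522 over SK10153 with SK10521 over SK10590 they numbered 165, 405 and 53, and for SK10590 over SK10153 with SK10522 over SK10521 they numbered 21, 74 and 1. With centred ratios these numbers were 142, 168 and 15. As these pairings use the same strain columns, they are not separate results.

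Across all gene list medians, 602 alternatives moved by less than the replicate spread and 100 by at least that much. Of the medians, 21 were at least 1 in size, and all of their 80 alternatives kept the sign, 70 of them at least 1 in size. Centring moved a ratio by at most 0.23, so it could not change the sign of medians chosen for that size. Smaller medians did change sign. That of tRNA modification genes for SK10522 over SK10153 went from 0.18 to -0.05 with centring. Of 216 alternatives for the features named at the ends of the ratios, 193 moved by less than the replicate SD and 23 by more. None changed sign, but neither centring nor a pseudocount could have changed it at ratios of this size. No paired analysis was possible because the table gives one mean per strain and no value per library. For the same reason leaving out single replicates and the planned tests on library columns were not run, and the genotype contrasts were not run because strain names are not paired with genotypes.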

Other observations

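The functional classes printed in the table were summarised in the same way as the fixed lists, a step added after the data were seen. Many classes were summarised in all 6 pairs, and only a few are named here. Of 304 features in the class of amino acid transport and metabolism, 58 were at least 2-fold higher and 21 lower in SK10521 than in SK10153, and 53 were higher and 10 lower in SK10522 (55 and 22, and 32 and 17, with centred ratios). Of 188 features of energy production, 12 were higher and 44 lower in SK10521 than in SK10153, and 10 were higher and 23 lower in SK10522 (12 and 46, and 8 and 41, with centred ratios). Of 85 features of nucleotide metabolism, 5 were higher and 21 lower in SK10521, and 3 were higher and 13 lower in SK10522 (4 and 23, and 2 and 18, with centred ratios). The mobile element class, with 29 features, had a median log2 ratio of -0.35 for SK10521 over SK10153, at percentile 0.10 of matched random lists, and of 0.41 for SK10522 over SK10521, at percentile 99.8. Both ratios use the SK10521 column. For SK10522 over SK10153 and over SK10590 the percentiles were 13.85 and 42.41. Of 32 features of cell motility, 6 were higher and 0 lower in SK10522 than in SK10521 (4 and 0 with centred ratios).

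The tests that follow were chosen after the results were seen, except those on short features and on the CV of other features in SK10521, whose outcomes were set out beforehand. The test on neighbours of tRNA genes was among those chosen afterwards, once a fixed list of genes beside tRNA operons had been seen. The interval for the tRNA sets was added after a first result. No explanation that names a genotype was tested, because no strain name is paired with one.

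Of the 39 tRNA value sets, 13 (33.3%, exact 95% interval 19.1% to 50.2%) were at least 2-fold higher in SK10521 than in SK10153. A bias for short features would raise other short features alike, but 7 of 75 other features of 150 bp or less were that much higher, or 9.33% (exact 95% interval 3.84% to 18.3%). Of the 33 of 100 bp or less, closer to tRNA in length, 4 were that much higher, or 12.1% (exact 95% interval 3.40% to 28.2%). That interval lies under the tRNA share but overlaps its interval, so a part played by length stays open. The intervals treat features as independent. One scaling factor for the strain would raise all features, and the median log2 ratio of features other than tRNA was 0.07 (0.065 before rounding). Reads moved between tRNA copies cannot account for all of it, since 6 tRNA features with values of their own, among them serV, leuW, leuU and thrU, were higher and lay beyond the spread. Whether the reads come from mature or precursor tRNA stays open, since the table has 1 value per gene.

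The sulfate and cysteine genes varied between the libraries of SK10521 and SK10522. Counting noise of weakly expressed genes would give other genes of like value the same CV, yet the list's median CV of 0.54 in SK10521 stood at percentile 100 of random lists matched on the value in that strain, whose median CV was 0.07 (0.065 before rounding). A library that differs in all genes would raise the CV of other called features. Their median CV in SK10521 was 0.10 over 574 features, against 0.54 for the list. A difference between cultures of one strain in these genes stays open, as does its origin.

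The his genes lay between the other strains in SK10522, with a median log2 ratio of -3.05 over SK10521. If 1 of its 3 libraries were a library of SK10521, that library alone would give each his gene a mean of at least the SK10521 mean divided by 3, whatever the others held, and that bound was at least 2.15 times the mean found in SK10522 for each of the 8 his genes. The highest CV of these genes in SK10522 was 0.12. If every library of SK10522 held a fixed share of SK10521 RNA and were otherwise like SK10590, the leu and ilv genes would be lower in SK10522 too, but their median log2 ratio of SK10522 over SK10521 was 0.34, and 11 of 13 were higher in SK10522. The other 2 were the leader peptide genes ilvL and ivbL, at -0.31 and -0.48. A share of SK10521 RNA in libraries that differ from SK10590 in other ways is not ruled out. What sets the 2 groups of operons apart stays open.

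One hypothesis was that transcripts running between tRNA genes and their neighbours may raise the neighbours in SK10521. The median log2 ratio of SK10521 over SK10153 of 59 features next to tRNA genes, without secG, was -0.05, at percentile 10.8 of matched random lists, with 4 higher and 8 lower. In SK10522 over SK10590 the same features had a median of 0.15, at percentile 97.2, with 1 higher and 0 lower. The rule written for this test asked for a median above nearly all random lists in SK10521 over SK10153, which was not met. The ratio of SK10522 over SK10590 was not part of that rule. As a set the neighbours were thus not raised in SK10521 over SK10153. Because members went both ways, the hypothesis stays open for single neighbours.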
